A study of Homo sapiens with 24 samples.

How the data were processed

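RNA was measured in the human embryonic stem cell line H7, in 2 control lines and 2 lines edited to lose BRAT1. Each line was sampled at day 0, as stem cells, and at day 14, as ventrally differentiated neural progenitors, with 3 biological replicates lettered A to C, which gives 24 libraries. Poly(A) RNA was prepared from Trizol extracts and made into libraries by Click-Seq, a method that keeps the strand of the RNA and joins the sequencing adapter by click chemistry. The authors named bcl2fastq 2.20.0, STAR 2.7.9a with the GRCh38 genome, featureCounts from Subread 2.0.1, and DESeq2 1.34.0 under R 3.5.1. The gene annotation release and the strand setting of featureCounts are not given in the sources used here.

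The deposited values are raw counts of reads per gene, 1 table for each of the 24 libraries, with 61248 features in each. They were checked to be whole numbers with no scaling, and 20966 of the features carry only an Ensembl identifier as their name. Features were matched by name to GENCODE release 29 on GRCh38, which placed 57070 of them, and these hold 90.18% of all counts. Unmatched features stayed in every fit and have no coordinates here. Release 29 is the annotation at hand and was not shown to be the release used for counting.

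The strand of the counts was checked on pairs of an antisense gene and the coding gene it overlaps. Every feature was classed by what lies on the other strand, as an exon overlap, a position within a gene body, a convergent or divergent gene within 5000 bp, or none of these. A feature was given a dominant opposite gene when the overlap of exons was at least 100 bp and at least 90% of it belonged to 1 gene, and 8231 features have such a gene. This reading, its thresholds and the tests that use it were chosen after seeing the data.

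Groups were compared with the edgeR 4.0.16 quasi-likelihood F test on raw counts, with TMM scaling, the filterByExpr filter and robust fits, under R 4.3.3. Benjamini-Hochberg adjusted p under 0.05 was the threshold. BRAT1 knockout was compared with control within each day, 6 libraries against 6. Day 14 was compared with day 0 within each genotype, and the interaction of genotype and day was tested, in 1 fit of all 24 libraries. Line 2 was compared with line 1 of each genotype and day, 3 libraries against 3, as the background between lines. Line was not a term in the main comparisons, so the 3 libraries of a line were treated as independent although each genotype has 2 lines. The tests were also tested on simulated data with added changes of 2, 4 and 8-fold.

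Named genes followed a fixed rule. For BRAT1 knockout against control, BRAT1 comes first, then the 8 largest positive and 8 largest negative log2 fold changes among genes past the threshold, with mean CPM of at least 2, the same direction in all 4 pairings of lines, and a symbol. For day 14 against day 0 in controls and for the interaction the rule takes 5 and 5. INTS11, CPSF3 and WDR73 were named as subjects of the series, and POU5F1, PAX6 and NKX2-1 as stage markers. From each list that passed its test come the 3 members with the smallest adjusted p, and from other lists up to 2. Any gene outside this rule is said to be chosen after its values were seen. Some features that meet the rule are not reported here, and they were not replaced.

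Gene lists numbered 28. They cover pluripotency, neural progenitors, ventral patterning, dorsal patterning, hindbrain and spinal cord, neurons, neural crest, glia, mesendoderm, mesenchyme, non-neural ectoderm, endothelium, Integrator subunits with WDR73 and SOSS complex members, cleavage and polyadenylation factors, snRNA genes, replication-dependent histones, immediate early genes, p53 targets, DNA damage repair, cell cycle, the integrated stress response, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, hypoxia and glycolysis, cholesterol synthesis, imprinted genes, zinc finger genes named ZNF, and clustered protocadherins. Lists with at least 3 tested members were tested with limma 3.58.1 camera on voom values, with the correlation between genes preset at 0.01, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance 1 way, was run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone.

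The comparisons, the tests, the rule for named genes, the lists and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a fold threshold, fits by line, a replicate block, thinning to 1407832 counts, all 24 libraries in 1 fit, and leaving out each line and each library in turn. Alternatives added after seeing the data were a fit without features above 1 percent of all counts, the opposite-strand reading of the lists, the wrong-strand percent of each library as a covariate, and a fit without the libraries above every control in that percent. The wrong-strand percent of a library is the median, over 89 pairs of genes, of the counts under a gene as a percent of the counts under the feature opposite it. RNA antisense to these genes would raise this percent as well as reads assigned to the wrong strand. These pairs have at least 500 CPM opposite and under 5 percent under the own name.

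Library totals ranged from 1407832 to 3726227 counts. A count of 0 allows up to 3 counts, which is at most 2.13 CPM per library at day 0 and 1.35 CPM at day 14. Folds against a group with no counts were computed as bounds against 3 counts over the group, and ratios against 1 to 3 counts carry 95% intervals. For the interaction the same was done for the ratio of the 2 folds, with an exact conditional interval. Intervals and floors cover counting error only, since reads were not told apart as molecules. Differences between groups of libraries outside the edgeR fits were tested by exact permutation, two-sided. Sequence-level data were not analysed here.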

Results

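Gene-level read counts were described for 24 poly(A) RNA libraries of H7 cells, a human embryonic stem cell line. BRAT1, a binding partner of the Integrator endonuclease INTS11, was knocked out in 2 lines, and 2 lines served as controls. Each line was sampled at day 0 as stem cells and at day 14 as ventrally differentiated neural progenitors, with 3 biological replicates, so each genotype and day has n = 6 libraries from 2 lines. At day 14, replicates A, B and C held 3682807, 3178583 and 3096534 counts in control line 1, and 3665783, 3396528 and 2228736 in control line 2. The knockout libraries of that day held 2688218, 2741254 and 3726227 counts in line 1, and 2857950, 3187929 and 3144724 in line 2. At day 0 the totals were 2059467, 1407832 and 1748877 in control line 1, and 1947485, 1608361 and 1446508 in control line 2. They were 1425141, 1743379 and 2143871 in knockout line 1, and 2106180, 1786126 and 1583588 in knockout line 2. Between 9299 and 15116 features had a count at day 0, and between 20769 and 25247 at day 14.

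For most pairs compared, the counts under a gene's name fit reads of the strand opposite that gene. Of 1836 pairs of an antisense gene and a coding gene with at least 100 counts, 1228 (66.9%) had more under the antisense gene, with a median ratio of 3.7. TALAM1, the antisense partner of MALAT1, held 6.91% of all counts, and MALAT1, an abundant nuclear long noncoding RNA, held 0.00444%. MT-ND6, which is encoded on the other strand from most other mitochondrial genes, held 6.38%. Ribosomal protein genes with no exon opposite, 54 in number, had a median of 16.8 CPM, but the 15 features opposite a ribosomal protein gene had a median of only 15.1 CPM, where this reading predicts high counts. Values are therefore given as counts under a name, with the gene opposite for those named by size, as subjects of the series or as stage markers, and they are not taken as a measure of the named gene's own mRNA. Counts under a name with no gene opposite could come from antisense RNA or from reads of the gene assigned to the wrong strand.

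**Figure D1:**
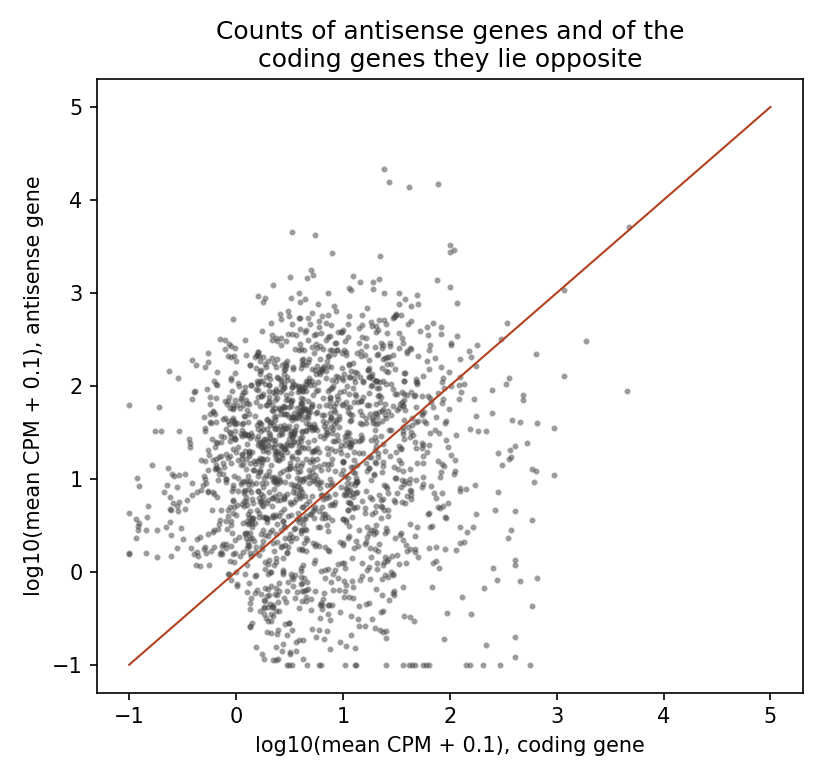
Each point is 1 of the 1836 pairs of an antisense gene and the coding gene it overlaps, with log10 of the mean CPM plus 0.1 under the coding gene on the x axis and under the antisense gene on the y axis. The line marks equal values, and 1228 pairs lie above it.

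The first comparison asked what BRAT1 loss changed in day 14 neural progenitors. BRAT1 (ENSG00000106009, GRCh38 chromosome 7, 2537877 to 2555727) had 252 ± 45.9 CPM (SD, n = 6) in controls and 46.2 ± 38.0 CPM (SD, n = 6) in knockouts. No gene lies opposite BRAT1 in the annotation, and whether this value reflects antisense RNA or wrong-strand reads of BRAT1 mRNA stays open. Counts under BRAT1 were 900, 868 and 836 in control line 1 and 803, 1077 and 414 in control line 2. They were 30, 21 and 63 in knockout line 1 and 248, 227 and 262 in knockout line 2. At day 0 they were 6, 0 and 0 in control line 1, 2, 0 and 0 in control line 2, 0 in every library of knockout line 1, and 8, 0 and 10 in knockout line 2. The day 14 log2 fold change was -2.47 (SE 0.57, edgeR adjusted p = 0.0111). It did not pass with counts summed per line (adjusted p = 0.354), without control line 1 (0.0914) or without control line 2 (0.0834), and its adjusted p over 28 alternatives ran from 8.13e-17 to 0.354.

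Of the 8 genes named for the largest rises in day 14 knockouts, 6 are genes of forebrain transcription factors or lie opposite 1. This grouping was made after the genes were ranked and was not tested as a list. DLX1 (ENSG00000144355, chromosome 2, 172084740 to 172089677), a ventral forebrain factor with no gene opposite, had 0.225 ± 0.262 CPM in controls and 57.8 ± 25.5 CPM in knockouts (SD, n = 6), a log2 fold change of 7.87 (SE 0.50, adjusted p = 7.57e-12). FEZF1-AS1 (ENSG00000230316, chromosome 7, 122303658 to 122310077), opposite the forebrain factor FEZF1, rose from 16.7 ± 3.04 to 391 ± 74.6 CPM (log2 fold change 4.53, SE 0.17, adjusted p = 2.61e-17). FOXD3-AS1 (ENSG00000230798, chromosome 1, 63320884 to 63324441), opposite the neural crest factor FOXD3, went from 48.1 ± 8.97 to 0.915 ± 1.02 CPM (log2 fold change -5.72, SE 0.48, adjusted p = 9.05e-09).

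The other genes with large rises were DLX2, DLX5, FEZF2, NKX2-1, CAPN6 and LINC00461. Counts under DLX2 (chromosome 2, 172099439 to 172102900) were at least 83.2-fold higher, at 12.4 ± 7.81 CPM in knockouts against 0 in controls, and DLX5 (chromosome 7, 97020392 to 97024950) was 240-fold higher (95% counting interval 66.1 to 1990). FEZF2, a forebrain factor, rose from 0.555 ± 0.495 to 28.8 ± 12.8 CPM (log2 fold change 5.52), and NKX2-1, a ventral forebrain factor gene opposite NKX2-1-AS1, from 0.689 ± 0.841 to 25.4 ± 13.1 CPM (5.11). CAPN6, of the calpain family, went from 2.93 ± 1.58 to 72.8 ± 29.4 CPM (4.60), and LINC00461, which overlaps MEF2C-AS2, from 0.718 ± 0.558 to 15.0 ± 4.53 CPM (4.31). The other large falls were under SGCA, LINC01257, LINC01124, ETV5-AS1, BHLHE40-AS1 and SALRNA1. SGCA, a muscle sarcoglycan gene opposite ENSG00000261959, was at least 60.4-fold lower, from 9.51 ± 6.82 CPM to 0. LINC01257 was 99.4-fold lower (33.7 to 485) and LINC01124 98.6-fold lower (27 to 820). Log2 fold changes were -4.92 for ETV5-AS1, -4.57 for BHLHE40-AS1, which overlaps BHLHE40, and -4.47 for SALRNA1. Of these 15 genes, 12 passed in every alternative that tested them. ETV5-AS1 (edgeR adjusted p = 0.0597) and LINC00461 (0.0515) did not pass with all 24 libraries in 1 fit, in each case the highest of the gene's alternatives. NKX2-1 did not pass without the knockout libraries high in wrong-strand percent, a fit that leaves 1 knockout library.

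**Figure D2:**
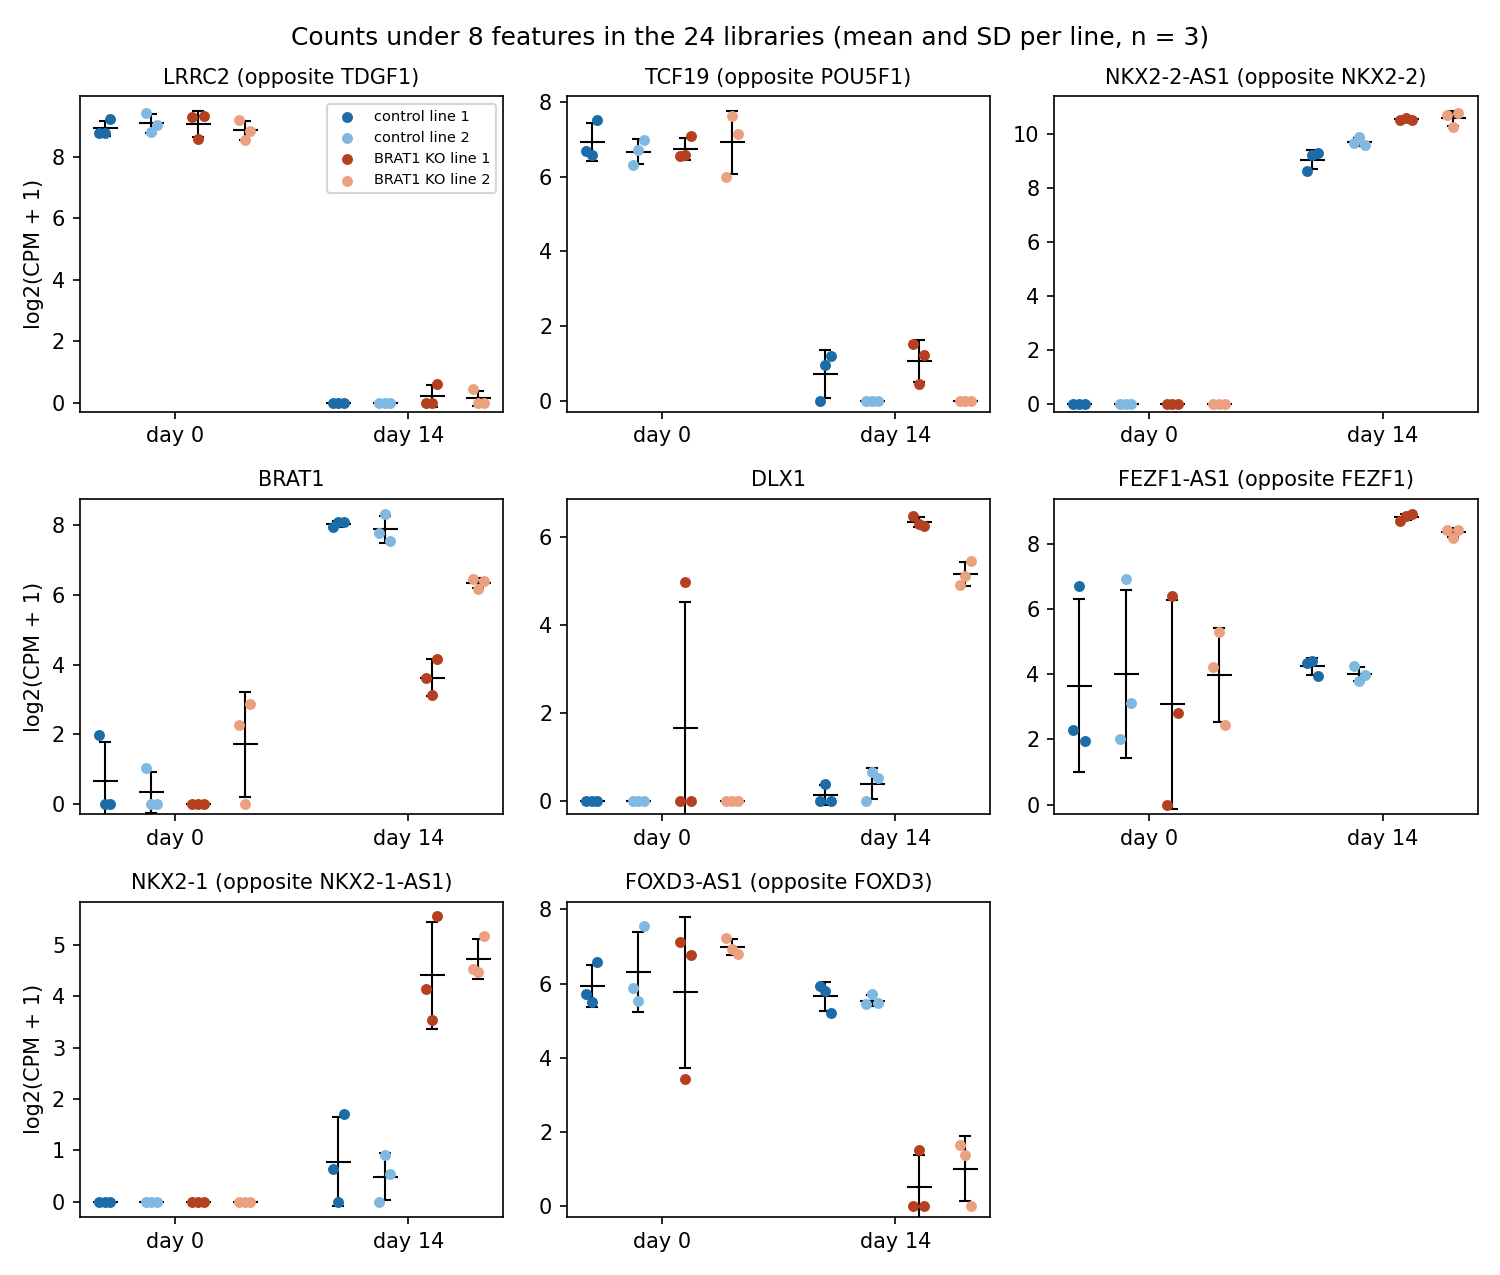
Counts are shown as log2 of CPM plus 1 for 8 features in every library, grouped by line and day, with the mean and SD of each line (n = 3). At day 14 DLX1, FEZF1-AS1 and NKX2-1 are higher and FOXD3-AS1 and BRAT1 lower in both knockout lines, while LRRC2 and TCF19 are near 0 in all lines.

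Among 16 measured neural progenitor genes, 9 rose in knockouts, 0 fell and 11 passed adjusted over the list alone. SIX3, an anterior forebrain factor, had a log2 fold change of 3.34 (SE 0.35, adjusted p = 1.43e-06), NES, the intermediate filament nestin, 1.30 (SE 0.19, 1.69e-05), and HES5, a Notch target, 1.78 (SE 0.27, 4.36e-05). The list passed camera (adjusted p = 1.08e-05), but not with an estimated correlation (adjusted p = 0.318). Of 13 ventral patterning genes 7 rose and 0 fell, with 7 adjusted over the list alone, led by DLX1, DLX5 and NKX2-1. That list also passed camera (adjusted p = 0.0067), and had an adjusted p of 0.331 with an estimated correlation. Of 11 imprinted genes 6 rose and 1 fell, with 7 adjusted over the list alone. DLK1, a Notch ligand relative (1.15), PEG10 (1.08) and NNAT (0.98) led that list, which passed camera (adjusted p = 0.0067) with an adjusted p of 0.331 under an estimated correlation. All 3 lists passed fry, at 0.00103 for neural progenitors and 0.00187 for ventral patterning and imprinted genes.

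The wrong-strand percent moved with genotype beside these 3 lists. Antisense RNA would raise it as well as reads assigned to the wrong strand, and these were not told apart. Counts under a gene as a percent of those opposite it were 1.10 ± 0.154 in controls and 1.56 ± 0.286 in knockouts (SD, n = 6, exact two-sided permutation p = 0.00866), a median shift of 0.42 (log2) over 89 gene pairs. That test treats the 3 libraries of a line as independent, although each genotype has 2 lines. Knockout line 1 replicates A and B had 1.29 and 1.18, against up to 1.28 in controls. With the wrong-strand percent as a covariate, an alternative added after seeing the data, neural progenitor genes had a camera adjusted p of 0.0369. Ventral patterning had 0.0751 and imprinted genes 0.106. The covariate moves with genotype, so it can also remove part of a genotype effect. A fit without the 5 knockout libraries above every control in that percent, also an alternative added later, leaves 1 knockout library, so its list tests are not used here. With the covariate DLK1 (adjusted p = 0.0759), PEG10 (0.0958), NNAT (0.279) and HES5 (0.108) did not pass, while SIX3, NES, DLX1, DLX5 and NKX2-1 did.

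Features that lie opposite a list member, a reading chosen after seeing the data, changed in other groups. All 3 features opposite mesenchyme genes fell, namely ACTA2-AS1 (-2.13) and FAS (-1.71), both opposite the smooth muscle actin gene ACTA2, and THY1-AS1 (-0.97). This list passed camera with the preset (adjusted p = 3.44e-05) and the estimated correlation (0.0257). It rests on ACTA2 and THY1 alone, since camera counts the 2 features opposite ACTA2 as separate members. Of 5 features opposite genes of the integrated stress response, 4 fell and 0 rose. ENSG00000264324 (-2.81) lies opposite MTHFD2 and ENSG00000276727 (-2.09) opposite SHMT2, both enzymes of mitochondrial folate metabolism, and VLDLR-AS1 (-1.58) opposite VLDLR. That list had adjusted p values of 0.000261 and, with an estimated correlation, 0.0257. SLC4A5 also lies opposite MTHFD2, and camera counts such features as separate members where both are tested. Opposite cholesterol synthesis genes 3 of 4 fell, ENSG00000261604 at HMGCS1 (-0.60), SREBF2-AS1 (-0.56) and ENSG00000223901 at LSS (-0.69), with an adjusted p of 0.0119 that became an adjusted p of 0.0909 with an estimated correlation. Opposite immediate early genes 2 of 4 fell, NR4A1AS (-1.92) and ENSG00000267598 at IER2 (-0.82), while IER3-AS1 (-1.24, adjusted p = 0.103) did not pass, with an adjusted p of 0.0158 for the list and an adjusted p of 0.159 with an estimated correlation. Adjusted over the list alone, 3, 4, 3 and 3 features of these lists passed. With the wrong-strand covariate the mesenchyme (adjusted p = 1.45e-05) and stress response (0.00105) features passed, and the cholesterol (0.17) and immediate early (0.146) features did not. The fit without the 5 libraries high in that percent leaves 1 knockout library and is not used for these lists.

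Most other patterning groups went both ways. Opposite ventral patterning genes, 2 of 7 features rose and 4 fell, with 6 adjusted over the list alone and a camera adjusted p of 0.216. INPP5A, opposite the ventral factor NKX6-2, fell (-1.75). NKX2-2-AS1, opposite the ventral factor NKX2-2, rose from 697 ± 192 to 1542 ± 180 CPM (1.13), and was named for this comparison after its values were seen. Of 7 dorsal patterning genes 1 rose and 2 fell, with 3 adjusted over the list alone, among them EMX2, a cortical factor (1.30), and ZIC4 (-1.34). Both measured hindbrain and spinal genes fell, EGR2 (-2.59, adjusted p = 0.0294) and HOXB3 (-3.08, adjusted p = 0.0361), with 2 adjusted over the list alone. Over the alternatives their adjusted p ranged from 0.000129 to 0.281 and from 4.54e-07 to 0.488. HOXB3 had 288 ± 71.0 and 423 ± 82.1 CPM in control lines 1 and 2, and 1.61 ± 2.79 and 83.3 ± 22.3 CPM in knockout lines 1 and 2 (SD, n = 3), and the knockout lines differed by 5.16 (log2, adjusted p = 0.000237). Of 15 neuron genes 5 rose and 3 fell, with 9 adjusted over the list alone, among them DCX (1.98) and NEUROD1, a neurogenic factor (-3.76). Of 6 neural crest genes 1 rose and 2 fell, TFAP2B (-4.44) and SOX10 (-2.85), with 3 adjusted over the list alone.

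**Figure D3:**
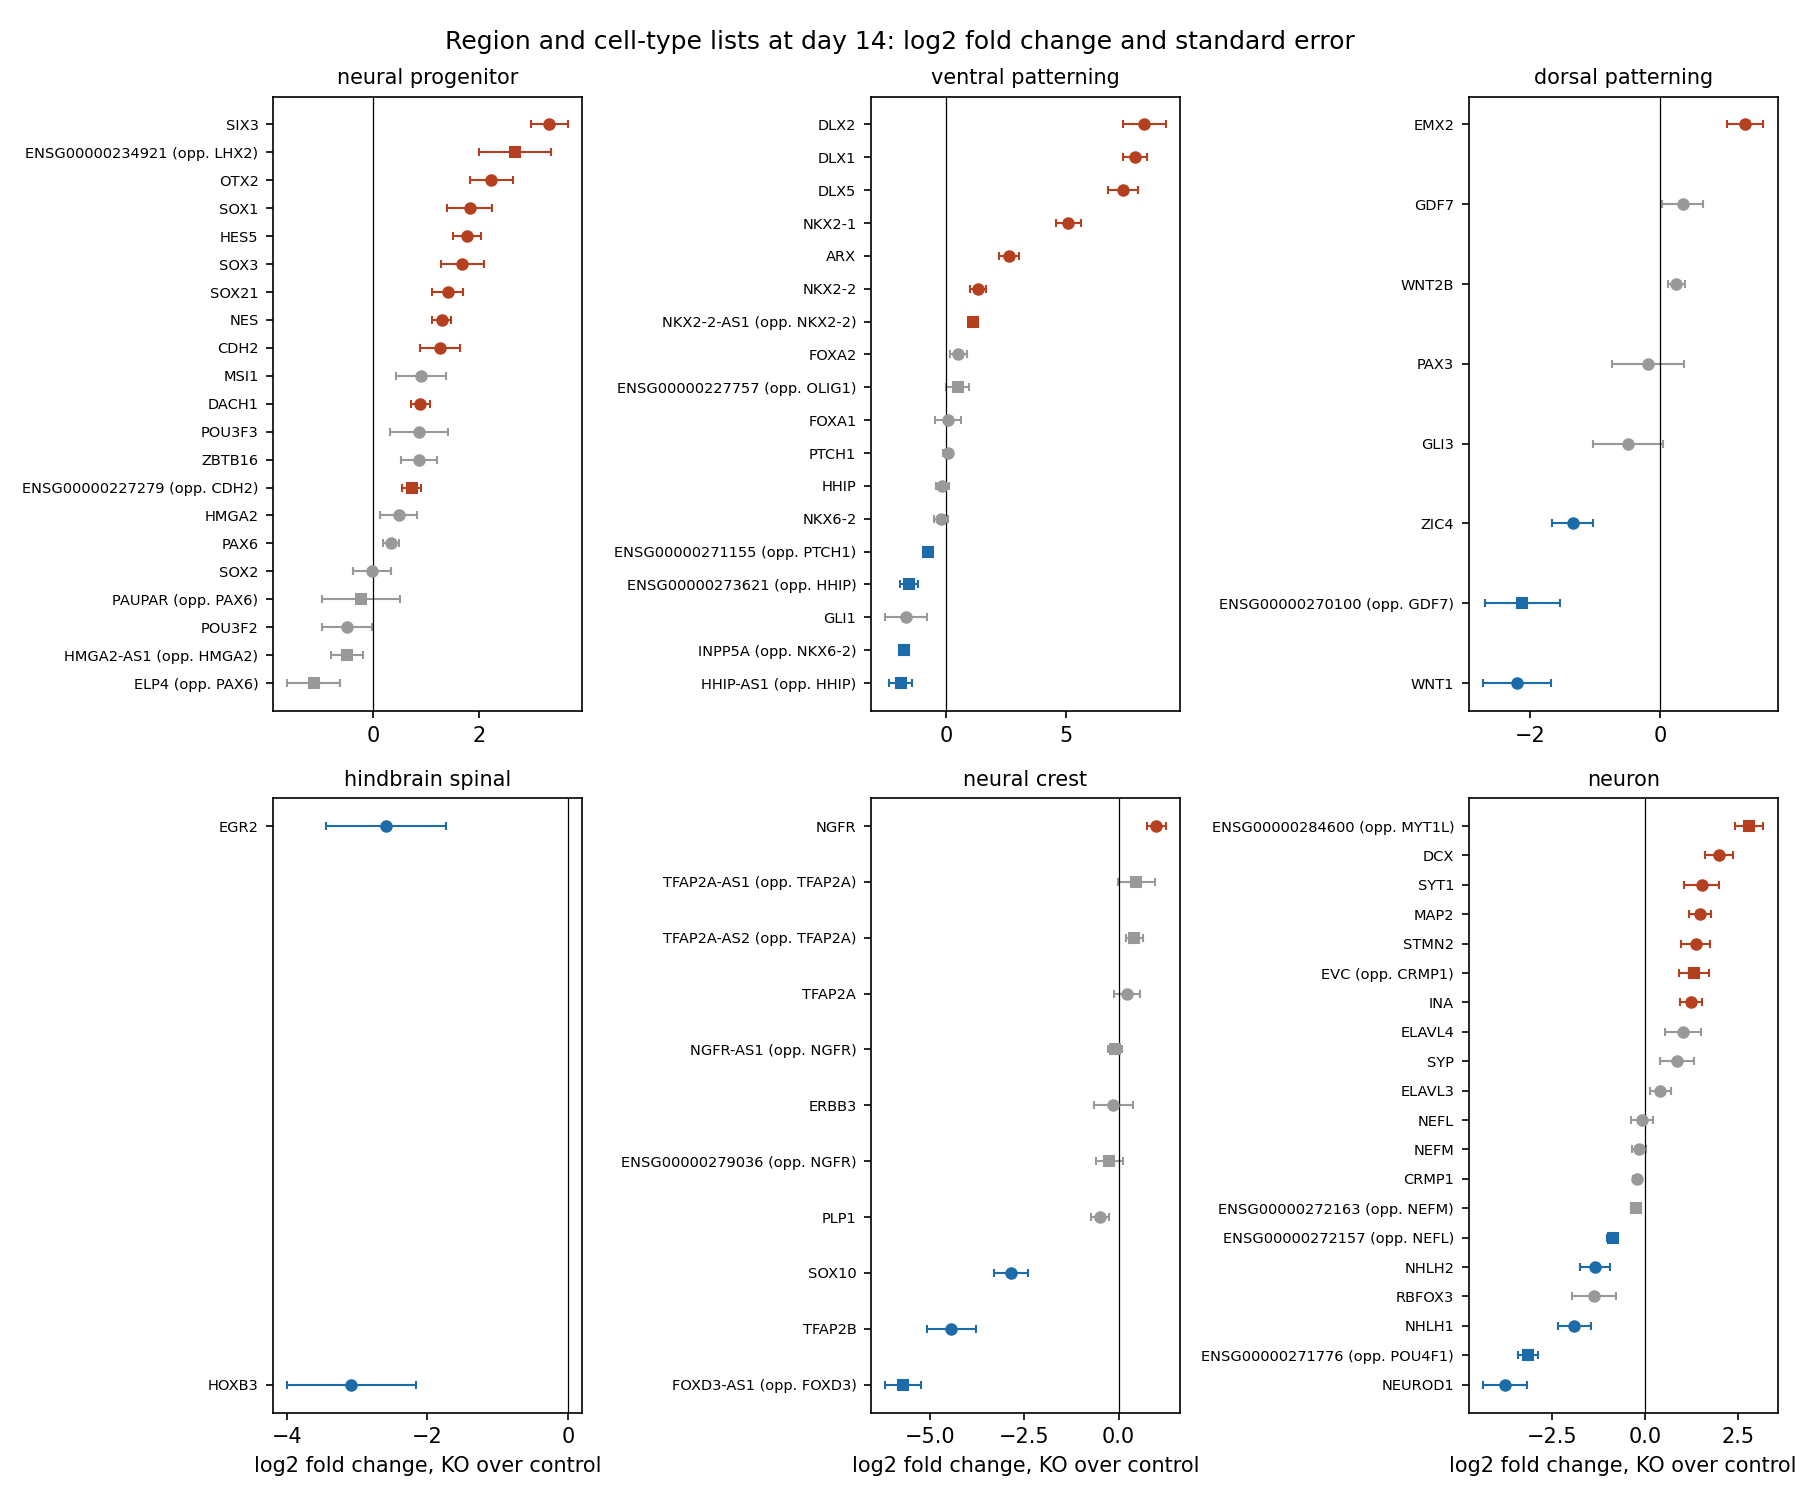
The x axis gives log2 fold changes of knockout over control at day 14, with SE, for reported members of 6 gene lists, as circles for counts under the member's own name and squares for features opposite a member. Red marks adjusted p under 0.05 and higher, blue lower and grey not passing. DLX2, DLX1 and DLX5 lie farthest to the right among ventral patterning genes, and FOXD3-AS1 farthest to the left among neural crest features.

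In the machinery named by the series, 2 of 10 genes of the Integrator list, which also holds WDR73 and members of the SOSS complex such as INIP, rose and 0 fell, with 3 adjusted over the list alone. INTS11 (ENSG00000127054, chromosome 1, 1311585 to 1324691), which overlaps PUSL1 on the other strand, had 106 ± 10.1 CPM in controls and 143 ± 28.2 CPM in knockouts (0.42, SE 0.15, edgeR adjusted p = 0.0449). This change is no more than the 0.42 shift of the wrong-strand percent. The adjusted p of INTS11 over 28 alternatives ran from 0.00622 to 0.623. INIP had 0.98. Of 13 cleavage and polyadenylation factors 2 rose and 0 fell, ZNF473 (0.98) and CPSF2 (1.05), with 1 adjusted over the list alone. The call was lost in 20 of 28 alternatives for CPSF2 and in 8 of 28 for ZNF473. Features opposite members, the reading chosen after seeing the data, did not only rise. Opposite genes of the Integrator list 0 of 5 rose and 1 fell, with 1 adjusted over the list alone. Opposite cleavage and polyadenylation factors 1 of 5 rose and 1 fell, with 2 adjusted over the list alone. WDR73, opposite SCAND2P, had 0.26 (adjusted p = 0.252), and CPSF3, at 1.12 ± 0.855 CPM in controls and 1.03 ± 0.943 CPM in knockouts, was below the filter. No member of the snRNA, histone, mesendoderm or endothelial lists passed the filter under its own name.

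Counts of rises and falls in the remaining lists were small. They were 0 and 1 of 7 pluripotency genes (NODAL, -1.07), 1 and 0 of 5 glia genes (GFAP, 1.06), 0 and 0 of 4 mesenchyme genes, and 1 and 0 of 1 non-neural ectoderm gene (GATA2, 2.64). They were 1 and 1 of 6 immediate early genes (CCN2, 1.49, and ZFP36, -1.57), 1 and 1 of 12 p53 targets (POLH, 0.76, and FAS), and 2 and 0 of 12 DNA damage repair genes (ATR, 1.71, and FANCD2, 1.69). In cell cycle genes they were 0 and 0 of 15, in the integrated stress response 0 and 1 of 7 (ATF5, -0.39), in mitochondrially encoded genes 1 and 0 of 13 (MT-ND6, 0.54), and in nuclear oxidative phosphorylation genes 0 and 0 of 10. In hypoxia and glycolysis genes they were 1 and 2 of 12 (KDM3A, 0.70, and SLC2A1, -1.53), in cholesterol synthesis 0 and 1 of 8 (INSIG1, -0.90), in zinc finger genes 23 and 11 of 190, and in clustered protocadherins 2 and 0 of 12 (PCDHA1, and PCDHA4 at 0.63). Some of these calls depended on the setting. The call was lost in 22 of 26 alternatives for FANCD2, 17 of 28 for ATF5, 15 of 28 for POLH, 12 of 28 for PCDHA4 and 5 of 27 for ATR. Adjusted over the list alone, 1 pluripotency, 1 glia, 0 mesenchyme, 1 non-neural ectoderm, 2 immediate early, 2 p53, 1 DNA damage repair, 0 cell cycle, 0 stress response, 1 mitochondrial, 0 oxidative phosphorylation, 3 hypoxia, 1 cholesterol, 29 zinc finger and 2 protocadherin genes passed. The median, mean and camera direction were not all of 1 sign for the mesenchyme, p53, cell cycle, oxidative phosphorylation, cholesterol and protocadherin lists. All these counts are under own names. Opposite cell cycle genes 0 of 4 features rose and 2 fell, with 3 adjusted over the list alone. EXOSC9, opposite CCNA2, had -0.64 (edgeR adjusted p = 0.00802), a call lost in 5 of 28 alternatives.

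In total 2474 of 11408 tested features changed at day 14 by edgeR, 1256 higher and 1218 lower, and DESeq2 called 3300. Of these 1425 changed at least 2-fold, and 2471 had the same direction in all 4 pairings of a knockout line with a control line. Across genes, which are not independent replicates, log2 fold changes of line pairs that share no library correlated with Pearson 0.597 and Spearman 0.549. The count was 1033 with the wrong-strand covariate, of which 854 were also among the 2474. It was 1552 without control line 1, 1266 without control line 2, and 241 with all 24 libraries in 1 fit, where the common coefficient of variation was 0.71 against 0.383 in the day 14 fit.

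The same comparison at day 0 asked what BRAT1 loss changed in stem cells. No feature passed in edgeR, 0 of 4832, with 99 at an unadjusted p under 0.05, and DESeq2 called 0 with 868 at that level. INTS11 had a log2 fold change of 0.91 (SE 0.29, adjusted p = 1.00). Counts under LRRC2, opposite the stem cell gene TDGF1, were 523 ± 101 CPM in controls and 513 ± 121 CPM in knockouts, and TCF19, opposite POU5F1, had 115 ± 36.8 and 120 ± 47.0 CPM (SD, n = 6). No list had a member past the threshold over all genes, and 1 of 5 genes of the Integrator list, INTS11, passed adjusted over the list alone. Mitochondrially encoded genes were lower by camera (13 genes, median -0.25, adjusted p = 0.029), a call lost with an estimated correlation (adjusted p = 0.883). On simulated data of this size edgeR recovered 6.0% of 2-fold, 32.8% of 4-fold and 65.2% of 8-fold changes. The log2 fold changes of line pairs that share no library had a Pearson correlation of -0.029 across genes. All 24 libraries in 1 fit gave 116 features, and no filter gave 13.

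The change from day 0 to day 14 in controls asked what differentiation altered. Counts opposite stem cell genes fell to near 0 and counts opposite ventral neural genes appeared. LRRC2 (ENSG00000163827, chromosome 3, 46515423 to 46580099), opposite TDGF1, a Nodal co-receptor, went from 523 ± 101 CPM to 0 (at least 3390-fold lower). TCF19, opposite the pluripotency factor POU5F1, went from 115 ± 36.8 to 0.373 ± 0.588 CPM (log2 fold change -8.60, SE 0.70, adjusted p = 2.27e-11), and is named through the reading chosen after seeing the data. NKX2-2-AS1 (ENSG00000258197, chromosome 20, 21511447 to 21512309) went from 0 to 697 ± 192 CPM (at least 2360-fold higher).

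Other large rises in controls were under OTX1, a forebrain factor (at least 542-fold), NR2F1, opposite NR2F1-AS1 (at least 377-fold), PAX8-AS1, opposite PAX8 (4710-fold, 846 to 186000), and INPP5A, opposite NKX6-2 (3590-fold, 644 to 142000). Other large falls were under LARP7, opposite MIR302CHG, the host of stem cell microRNAs (log2 fold change -12.18), C13orf42 (-12.08), LINC01194 (-9.84) and CDKL4 (829-fold lower, 283 to 4030). All 10 genes passed in every alternative that tested them. Counts under POU5F1, opposite TCF19, fell (-4.30) and those under PAX6, opposite ELP4, rose (3.04, adjusted p = 2.59e-06), while NKX2-1 did not pass (adjusted p = 0.0508, range over alternatives 0.0328 to 0.596).

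Of 3 features opposite pluripotency genes all fell (camera adjusted p = 2.2e-07, and 0.00065 with an estimated correlation), and of 7 opposite ventral patterning genes all rose (1.99e-05 and 0.0118), with 3 and 7 adjusted over the list alone. INPP5A and the feature ENSG00000271155 opposite PTCH1, the Hedgehog receptor (5.97), were among them. Of 5 features opposite stress response genes 3 fell, ENSG00000264324 and SLC4A5, both opposite MTHFD2 (-2.33 and -2.48), and ENSG00000276727 opposite SHMT2 (-1.04), with 4 adjusted over the list alone. The call of ENSG00000276727 was lost in 20 of 39 alternatives. The stress response list had a camera adjusted p of 0.0342 and an adjusted p of 0.189 with an estimated correlation. Camera counts both features opposite MTHFD2 as separate members of it. Under their own names 11 of 16 neural progenitor genes rose and 0 fell, with 13 adjusted over the list alone, among them DACH1 (2.63) and HES5 (at least 74-fold). Of 15 neuron genes 8 rose and 1 fell, with 9 adjusted over the list alone, among them MAP2, a dendritic protein (84.9-fold, 23.3 to 704), and CRMP1 (2.67). Of 173 zinc finger genes 68 rose and 9 fell, with 78 adjusted over the list alone. These 3 lists passed camera at adjusted p values of 0.0345, 0.0439 and 0.020, and with an estimated correlation had adjusted p values of 0.248, 0.346 and 0.248. The median, mean and camera direction were not all of 1 sign for the pluripotency, mesenchyme, Integrator, DNA damage repair, cell cycle, stress response and hypoxia lists, none of which passed under their own names.

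In controls 4699 of 10971 features changed, 3115 higher and 1584 lower, and DESeq2 called 7288. Without control line 2 the count was 2926. RLE scaling moved the median of all genes by 0.216 (log2), with 3654 higher and 1349 lower.

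In BRAT1 knockout lines the same change gave 5077 of 10971 features, 3265 higher and 1812 lower. LRRC2 was 3160-fold lower (1080 to 15300) and NKX2-2-AS1 at least 5530-fold higher, reaching 1542 ± 180 CPM. NKX2-1 was at least 95.8-fold higher than the 0 counts of day 0. Of 16 neural progenitor genes 14 rose and 0 fell (camera adjusted p = 0.00015, and 0.0459 with an estimated correlation), with 14 adjusted over the list alone. Of 11 ventral patterning genes 9 rose and 0 fell, with 9 adjusted over the list alone (adjusted p = 0.000219, and an adjusted p of 0.0516 with an estimated correlation). Imprinted genes (8 of 9 rose, adjusted p = 0.006), neuron genes (12 rose and 2 fell of 15, 0.0137) and zinc finger genes (73 rose and 6 fell, 0.006) passed camera, and with an estimated correlation had adjusted p values of 0.0723, 0.22 and 0.22. Opposite immediate early genes 3 of 4 features fell, led by IER3-AS1 (-6.77), with an adjusted p of 0.000607 and 0.00952 with an estimated correlation. Opposite cell cycle genes 3 of 4 fell, led by EXOSC9 at CCNA2 (-2.28), with an adjusted p of 0.022 and an adjusted p of 0.0942 with an estimated correlation. Opposite pluripotency genes 3 of 3 fell, opposite ventral patterning genes 7 of 7 rose and opposite stress response genes 4 of 5 fell, and these lists passed with either correlation. Adjusted over the list alone, 8 imprinted, 14 neuron and 79 zinc finger genes passed, as did 3 features opposite immediate early and 3 opposite cell cycle genes.

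Between the genotypes 3517 features changed with differentiation in both, 2203 higher in both, 1305 lower in both and 9 in opposite directions. Independent changes would give 927 and 261.6. Fold changes of control and knockout correlated with Pearson 0.758 and Spearman 0.762 across genes. DESeq2 called 8947 features in knockouts, and RLE scaling moved the median of all genes by 0.392 (log2).

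The interaction asked whether the change with differentiation differed between genotypes. It passed for 161 of 10971 features, 62 higher and 99 lower in knockouts, and with RLE scaling, which moved the median by 0.176 (log2), for 76 higher and 70 lower. The count was 40 and 16 without control lines 1 and 2, 23 and 58 without knockout lines 1 and 2, and 28 with counts summed per line. It was 259 without control line 1 day 0 replicate A, and between 91 and 107 without any 1 day 14 library other than knockout line 2 replicate A. Named by fitted value, the change was higher in knockouts under CAPN6 (2690-fold, 446 to 107000, adjusted p = 0.000463), POU3F4, a neural POU factor gene opposite ENSG00000279437 (at least 110-fold), LINC01289 (at least 60.6-fold), JPH2 (at least 61.6-fold) and ZSCAN25 (at least 49.7-fold). It was lower under PAX8-AS1 (1900-fold, 332 to 75700), HMGB3P9 (log2 value -8.81), CALM2P2 (at least 46.4-fold), LINC01257 (323-fold, 69.4 to 1890) and POPDC3 (at least 28.6-fold). Opposite stress response genes 3 of 5 features were lower, ENSG00000264324 (-2.98) and SLC4A5 (-2.82) at MTHFD2 and ENSG00000276727 (-2.25) at SHMT2 (list adjusted p = 9.77e-05, and 0.0298 with an estimated correlation). These 3 features rest on MTHFD2 and SHMT2 alone, since camera counts both features at MTHFD2 as separate members. Opposite immediate early genes 2 of 4 were lower, NR4A1AS (-2.17) and ENSG00000267598 at IER2 (-1.25), with adjusted p values of 0.00109 and, with an estimated correlation, 0.0257. Opposite mesenchyme genes THY1-AS1 (-1.18) and ACTA2-AS1 (-2.69) were lower, with an adjusted p of 0.00278 and an adjusted p of 0.0577 with an estimated correlation. Adjusted over the list alone, 3, 3 and 2 features of these lists passed. No single neural progenitor gene (16) or ventral patterning gene (11) passed, 0 in each by edgeR, and adjusted over the list alone 1 and 0 did. This absence says little. On simulated data of this size edgeR recovered 0% of 2-fold, 11.9% of 4-fold and 33.3% of 8-fold interaction changes. NKX2-1, with 0 counts at day 0, had an SE of 7351 and could not pass. As lists the neural progenitor and ventral patterning genes were higher by camera (adjusted p = 0.000113 and 8.82e-07, and 0.0291 and 0.0074 with an estimated correlation). These tests were not adjusted for the wrong-strand percent, which rose in knockouts at day 14 and moves with counts in the same direction. Of the 10 named features 8 have a day 0 group with 0 or 1 counts, LINC01257 has 3 counts in day 14 knockouts, and none of the 10 passed in every alternative. LINC01289 did not pass without control line 2 day 0 replicate B (adjusted p = 1) and LINC01257 without knockout line 2 day 0 replicate C (adjusted p = 0.482), within ranges of 3.23e-07 to 1 and 0.000347 to 1.

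Lines of the same genotype were compared as background. At day 0 line 2 against line 1 gave 0 of 7165 features in controls (267 at an unadjusted p under 0.05, 12 by DESeq2) and 0 in knockouts (198, and 2 by DESeq2), both by edgeR. At day 14 it gave 16 of 15000 features in controls, 14 higher and 2 lower, and 184 in knockouts, 124 higher and 60 lower. Counts under BRAT1 were 11.9 ± 4.67 CPM in knockout line 1 and 80.4 ± 8.18 CPM in knockout line 2 (SD, n = 3). Without knockout line 1 replicate C the control count, which shares the fit's spread, was 25, and without control line 1 replicate A it was 10. The knockout count was 116 without line 1 replicate B, 289 without line 1 replicate C, 109 without line 2 replicate A and 117 without line 2 replicate C.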

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

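The correlation of line pairs, the thinning test, the wrong-strand tests per sense read, the test of convergent neighbours and the BRAT1 test were chosen after their results were seen.

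Members of the neural progenitor, ventral, dorsal, hindbrain and spinal, neural crest and neuron lists differed between genotypes at day 14, 32 called members of these 6 lists under their own names, 23 of them higher and 9 lower. Among features opposite members of these lists 6 were higher and 9 lower. The tables argue against 1 line as the source (0.597, the lower correlation across genes of line pairs that share no library, against -0.019 within genotype) and against library depth, since 78.1% (25 of 32) passed in the same direction after thinning, and the other 7 were no longer tested. Of all 2474 calls 1949 were still tested, and 1693 passed in the same direction. They argue against a gained or lost whole chromosome as the source of the calls (largest excess of 0.92 percentage points among called genes). Median log2 fold changes were highest for chromosomes X (0.28) and 20 (0.197), against 0.136 or less for each other chromosome. A change of part of a chromosome, or in part of the cells, was not tested. A higher rate of wrong-strand reads is argued against for the 9 members that fell, since the shift of 0.42 (log2) is upward. With the covariate 77.8% (7 of 9) passed in the same direction, with a median log2 fold change of -3.22 (median SE 0.86) against -2.59 (0.52). Such a higher rate is also argued against for 8 of the 23 that rose. Their counts could still be wrong-strand reads of more mRNA. These 8, 13.6% of the 59 tested members where the shift gives at most 5% (one-sided binomial p = 0.00886), exceed 1.24, the 95th percentile of the shift over gene pairs, by more than 2 SE. That binomial test treats the members as independent, although genes of a list can move together. For the other 15 that rose a higher rate cannot be told apart, because 13.3% (2 of 15) passed with the covariate, which moves with genotype, and the median was 0.87 (median SE 0.41) against 1.35 (0.29). A difference between the 4 lines that is not due to genotype cannot be told apart, because the other groupings of the lines in pairs called 0 features and only 3 groupings exist. A shift in cell types or regions of the cultures after BRAT1 loss stays a hypothesis beside it, since each genotype has 2 lines.

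Features without an opposite exon were higher in knockouts at day 14. The median log2 fold change was 0.309 for those with no gene opposite, 0.277 for those within a gene body, 0.297 with a divergent and 0.22 with a convergent neighbour, against -0.042 for features with an opposite exon, and the tests below are on those with no gene opposite. Counts under a gene per count opposite it rose by 0.42 (SE 0.043), at least the 0.351 between the classes. Wrong-strand reads could be the source, and so could antisense RNA, which would raise this measure too. Lower abundance is argued against by a difference of 0.266 (SE 0.027) within bins of matched CPM. Features with a convergent gene within 5000 bp had 0.22 (SE 0.034), below 0.309, which argues against read-through from genes that near. Convergent genes farther away were not classed, so read-through over longer distances stays open. Differences between libraries unrelated to genotype cannot be told apart. The class's share of counts was 2.96% ± 0.64 in knockouts and 2.25% ± 0.255 in controls (SD, n = 6, exact two-sided permutation p = 0.0281), but that test treats the 3 libraries of a line as independent, and 2 knockout libraries, line 1 replicates A and B (2.28% and 2.39%), lie within the controls. Ribosomal protein genes with no exon opposite had 0.103 (SE 0.059, 44 genes), below the 0.309 of the class by more than 2 SE. The rule written before this result took that as against more sense reads on the wrong strand. The later test per sense read, above, went the other way. The sense reads of the ribosomal protein genes were not counted, so their test cannot decide and this explanation stays open. Genomic DNA and unspliced RNA also stay open.

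Counts under BRAT1 at day 14 were 252 CPM in controls although no gene lies opposite. At the rate of wrong-strand reads of GAPDH, 0.372%, they would need 67700 CPM of BRAT1 mRNA. At the 1.10% of the 89 gene pairs in controls they would need 22900 CPM. Both are above the 11400 CPM counted opposite GAPDH but below the 97700 CPM of the highest feature, which is a lenient limit. The rate at BRAT1 itself was not measured, so antisense RNA at BRAT1 and wrong-strand reads of BRAT1 mRNA cannot be told apart. An effect of the edited locus on a transcript across it also stays open and was not tested.

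In 7 of 60 groups of 6 libraries tested, the gap between 1 library and the others was large for the range of the group, where chance gives about 1 in 20. CAPN6 had 132 CPM in knockout line 1 day 14 replicate C, against 54.7 to 70.3 CPM in the others. SGCA had 22.8 CPM in control line 1 day 14 replicate A, against 4.36 to 9.44. In knockouts at day 14, LINC01257 had 0.941 CPM in line 2 replicate B and ETV5-AS1 had 1.49 CPM in line 1 replicate A, against 0 in the other 5 libraries of each. In controls at day 0, PAX8-AS1 had 0.486 CPM in line 1 replicate A and INPP5A 0.71 CPM in line 1 replicate B, again against 0. C13orf42 had 0.883 CPM in control line 2 day 14 replicate B, against 0 to 0.273. These last 5 values are 3, 4, 1, 1 and 3 counts, while a count of 0 allows up to 3, so none but ETV5-AS1 exceeds that limit.

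The change with differentiation differed between genotypes for 161 features by the interaction test. It was higher in knockouts by 2690-fold for CAPN6, and by at least 110-fold for POU3F4, 60.6-fold for LINC01289, 61.6-fold for JPH2 and 49.7-fold for ZSCAN25. It was lower by 1900-fold for PAX8-AS1, by 323-fold for LINC01257, by at least 46.4-fold for CALM2P2 and 28.6-fold for POPDC3, and HMGB3P9 had a log2 value of -8.81. HMGB3P9 and POPDC3 each did not pass in 18 of the fits that leave out 1 library, JPH2 in 12 and ZSCAN25 in 7.

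Other splits of the same libraries were counted for each comparison. For knockout against control at day 14 the real split was the only 1 of 100 with as many features (2474, highest other 39), for differentiation in controls 1 of 100 (4699, highest other 336) and in knockouts 1 of 100 (5077, highest other 926), so chance is excluded for these. For the interaction 3 of 100 splits gave as many features (161, highest other 254). That share is under 0.05, but chance is not taken as excluded, since other splits exceeded the real count. These splits also treat the libraries of a day as exchangeable, although all 12 libraries at day 0 correlated best with 1 of their own letter. Splits between genotypes mix the libraries of a line, so they do not exclude a difference between lines, of which each genotype has 2. For knockout against control at day 0 the real count was 0, so all 100 splits give at least as many and the share decides nothing. Another split gave 102 features, and what sets its libraries apart was not tested. For line 2 against line 1, 10 splits are too few for a share under 0.05. There the real and highest other counts were 0 and 0 in controls and in knockouts at day 0, each with 10 of 10 splits as large. At day 14 they were 16 and 3 in controls and 184 and 11 in knockouts, each with 1 of 10.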

How the results depend on the processing

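The alternatives with wrong-strand percent, those without features above 1 percent of counts, and the opposite reading of lists were added after the results were seen, and the others were planned. Over 284 values of named genes, 9513 alternative values were computed. Of these 8617 were on the same side of the threshold and in the same direction, 660 no longer passed, 160 newly passed, 76 moved without a test call and 0 reversed. Causes were not tested except where fewer libraries or genes enter by construction. Depth limits most at day 0, where 3 counts are up to 2.13 CPM.

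For knockout against control at day 0 (0 features), no filter gave 13, counts summed per line 1, the fit without control line 1 gave 1 and all 24 libraries in 1 fit gave 116. At day 14 (2474), a 2-fold threshold gave 1425, leaving out control line 1 gave 1552 and control line 2 gave 1266, and all 24 libraries in 1 fit gave 241, under a spread shared with day 0. The wrong-strand covariate gave 1033, and the fit without libraries above every control in wrong-strand percent gave 1115. That fit leaves 1 knockout library, assumed to vary like the controls.

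For differentiation, DESeq2 gave 7288 in controls and 8947 in knockouts, no filter gave 8739 in knockouts, and the fit without control line 2 gave 2926 in controls. For the interaction (161), DESeq2 gave 549, no filter 792, the contrast of line means 96, counts summed per line 28, limma with duplicate correlation 315, thinning 92 and line as a fixed block 73. It gave 40 and 16 without control line 1 and 2, and 23 and 58 without knockout line 1 and 2. Fits without features above 1 percent of counts gave 2490 at day 14, 4902 and 5323 for differentiation and 155 for the interaction.

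Between lines at day 0, controls gave 12 with DESeq2 and 9 with no filter, and knockouts 2 with DESeq2, 4 with no filter and 1 with a replicate block. At day 14, controls gave 42 with no filter and knockouts 338 with DESeq2.

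Counts of lists past the threshold also moved. Under their own names at day 0 the 1 list became 0 with an estimated correlation, 0 with fry, 0 without control line 1 and 0 without knockout line 2, and the 0 lists of the opposite reading became 1 without knockout line 2. At day 14 the 3 own-name lists became 0 with an estimated correlation, 7 with fry, 5 without knockout line 1 and 1 with the wrong-strand covariate. The 4 opposite lists became 2 with an estimated correlation, 11 with fry and 2 with the covariate. Lists are not counted for the fit without the libraries high in wrong-strand percent, which leaves 1 knockout library. For differentiation in controls, 3 own-name lists became 0 with an estimated correlation, 17 with fry, 0 without control line 1 and 6 without knockout line 1, and 3 opposite lists became 14 with fry and 7 without control line 2. In knockouts 5 own-name lists became 1 with an estimated correlation and 18 with fry, and 5 opposite lists became 13 with fry. For the interaction 2 own-name lists became 5 with fry, 4 with a replicate block, 4 without control line 2 and 5 without knockout line 1, and 3 opposite lists became 5 without knockout line 1.

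The correlation of line pairs was -0.005 crossed and -0.021 at CPM of at least 10 at day 0, against -0.029, and 0.626 and 0.675 at day 14, against 0.597.

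Leaving out each library in turn gave 0 to 0 features at day 0, 2113 to 2551 at day 14, 4558 to 5240 for differentiation in controls and 4874 to 5680 in knockouts, and 91 to 259 for the interaction. It gave 0 to 1 and 0 to 0 between lines at day 0 in controls and knockouts, and 10 to 25 and 109 to 289 at day 14. The interaction fell to between 91 and 107 without any day 14 library other than knockout line 2 replicate A, and was 259 without control line 1 day 0 replicate A. Between lines at day 14 the values outside 1.5 times were 10 without control line 1 replicate A and 25 without knockout line 1 replicate C in controls. In knockouts they were 116 and 289 without line 1 replicates B and C, and 109 and 117 without line 2 replicates A and C.

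Replicate letters do not pair the libraries at day 14, where 2 of 18 same-letter correlations exceeded 0.1. At day 0, 13 of 18 did, and all 12 libraries correlated best with 1 of their own letter. A replicate block gave 0 features at day 0, 2256 at day 14, 4877 and 5279 for differentiation and 125 for the interaction.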

Other observations

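The genes of this part and the reading of features opposite a list member were chosen after the values were seen. Counts opposite further neural genes differed between genotypes at day 14. ENSG00000271776, opposite POU4F1, a factor of sensory neurons, fell from 436 ± 31.7 to 49.8 ± 25.7 CPM (SD, n = 6, log2 fold change -3.15, edgeR adjusted p = 1.25e-06) and passed in all 28 alternatives. PAX8-AS1 (chromosome 2, 113211522 to 113276581), opposite PAX8, a factor of the midbrain-hindbrain border and otic placode, fell from 455 ± 61.7 to 25.1 ± 19.9 CPM (-4.20, adjusted p = 0.000486). Both falls differed in size between the knockout lines. Line 2 was above line 1 by 1.09 (log2, edgeR adjusted p = 0.00801) under ENSG00000271776 and by 2.48 (0.000614) under PAX8-AS1. ENSG00000284600, opposite the neuronal factor MYT1L, rose from 3.94 ± 2.51 to 27.3 ± 10.3 CPM (2.79, adjusted p = 5.5e-06), and ENSG00000234921, opposite the forebrain factor LHX2, from 1.08 ± 1.19 to 7.19 ± 3.75 CPM (2.69, adjusted p = 0.00558).

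At day 14, ENSG00000271155, opposite the Hedgehog receptor gene PTCH1, had a log2 fold change of -0.76 (adjusted p = 0.00149), and ENSG00000273621, opposite HHIP, had -1.54 (adjusted p = 0.00479). Under their own names PTCH1 (0.07, adjusted p = 0.851), HHIP (-0.16, 0.714) and GLI1 (-1.68, 0.204) did not pass, and no list of Hedgehog genes was tested. The knockout lines differed here too. Line 2 was above line 1 by 0.80 (log2, edgeR adjusted p = 0.00248) under ENSG00000271155 and by 4.60 (0.00173) under GLI1. Opposite DNA damage repair genes 1 of 5 features rose, TUBGCP4 at TP53BP1 (0.57), and 3 fell, among them FANCD2OS at FANCD2 (-0.83), with 5 adjusted over the list alone and a camera adjusted p of 0.196 for the list. Opposite p53 targets 2 of 4 fell, ENSG00000271730 at SESN1 (-1.41) and XPC-AS1 at XPC (-0.47), with 3 adjusted over the list alone and a camera adjusted p of 0.216.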
